A study of Bos taurus with 12 samples.

How the data were processed

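RNA was measured in skin explants of Holstein heifers, half-sisters that each had 1 of 2 bulls heterozygous for the slick allele as sire. Per the labels' protocols, each explant was cultured for 36 h at 38.5 °C in medium with 50 ng/mL ovine prolactin and 0.4 ug/mL hydrocortisone, and polyA RNA was sequenced in read pairs. The labels gave 12 libraries, 6 from slick and 6 from non-slick heifers. All 12 explants received prolactin, so the response to prolactin itself was not measured, and the comparison is between genotypes in its presence. Explants of each heifer had a well of their own. Each library name holds a number of its own, but the labels do not say that it stands for a heifer, so p-values measure the spread between these libraries. The labels did not tie libraries to sires, culture plates or sequencing batches, and none of these entered a model.

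The deposited values were raw read counts per gene, whole numbers that differed in their total between libraries. The submitters' processing notes name STAR, FastQC, HTSeq and R 4.3.1, without a role or order. The genome build and the strand setting of the counting were not given in the sources used here, so counts of overlapping or antisense genes, and of genes with near-identical copies, are uncertain. The table held 27607 genes under Ensembl cattle gene IDs. The files do not pair these IDs with names. The reference used here, a RefSeq table of 37063 cattle genes, gave an Ensembl ID for 0 of them, so that no match was possible and 0 of the 27607 IDs were matched. The prolactin receptor gene, its neighbours, mitochondrially encoded genes and the gene lists fixed for hair, gland, immune and signalling functions were for this reason not analysed here.

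Total counts ran from 10903164 in slick 2 to 22036904 in slick 5. Genes with enough counts by the edgeR function filterByExpr were kept, 14594 in all, which held at least 99.9% of the counts of each library. Libraries were scaled by the trimmed mean of M values (TMM), and genotypes were compared with the quasi-likelihood F-test of edgeR 4.0.16 with robust estimation, in R 4.3.3. Genotype was the sole term, p-values were adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. Log2 fold changes are slick minus non-slick, and CPM are counts scaled by the TMM-adjusted library size. Principal components used log2 CPM with a prior count of 2. Measures of whole libraries were compared with two-sided exact permutation tests over all 924 splits. Alternatives used DESeq2 1.42.0, limma 3.58.1 and sva 3.50.0, other scaling factors and filters, a replicate block, and each library left out in turn. These choices were fixed before the data were examined, apart from the principal components and their tests, which were not among the results fixed beforehand. The count at an unadjusted p of 0.05, the intervals against fold limits, the genes without overlap between groups and the spread within groups were added after no gene had passed the threshold.

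Genes were to be named by symbol if they passed the threshold, and otherwise filled to 10 by the smallest unadjusted p. Without symbols, the 10 are summarised, and 2 IDs in each direction are given. No pair held the same library sequenced again. The chi-square per degree of freedom between libraries was at least 18.6 over all pairs and at least 30.8 within a group, where sampling noise alone gives about 1. This does not exclude separate explants of 1 heifer.

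The tests were tried on simulated counts with the means, dispersions and library sizes of these data, in 5 draws with 200 changed genes each among 14594. edgeR called 22.1% of the genes changed 1.5-fold, 60.6% of those changed 2-fold and 86.4% of those changed 4-fold, and 4.10% of its calls were false. DESeq2 called 33.4%, 71.3% and 90.6% of these genes, and 17.0% of its calls were false. Both shares would differ with another number of changed genes. edgeR filtered each simulated table again, while DESeq2 was run without that filter. A changed gene that the filter removed counted as not called, so part of the gap in genes called may come from the filter.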

Results

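The SLICK1 allele is a variant of the prolactin receptor gene found in cattle with a short, sleek coat. Skin explants of slick and non-slick half-sister heifers were cultured with prolactin for 36 h, and gene expression was compared between the genotypes in 6 slick and 6 non-slick libraries. Total counts were 18775238 ± 4052962 per library in slick explants (SD, n = 6) and 18115125 ± 2617786 in non-slick explants (SD, n = 6). The difference in totals was within the spread of the libraries (exact permutation test, two-sided, p = 0.758, adjusted over 3 measures p = 0.758). The 10 most abundant genes took 5.67% of the counts in slick and 6.10% in non-slick explants (exact permutation p = 0.165, adjusted p = 0.494). A count was found for 17106.5 genes per slick library and 17245.3 genes per non-slick library (exact permutation p = 0.571, adjusted p = 0.758). The direction of this difference turned when at least 10 counts were asked for, with 14658.2 genes in slick and 14537.7 in non-slick libraries, and when slick 2 was left out, with slick minus non-slick at 14.1 genes.

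No gene differed in expression between slick and non-slick explants at the threshold set for the comparison. With the quasi-likelihood test of edgeR, 0 of the 14594 genes tested passed an adjusted p of 0.05, and the smallest adjusted p was 0.650. At an unadjusted p of 0.05, edgeR listed 811 genes, 442 higher and 369 lower in slick explants. Uniform p-values would give 729.7, and the median of other drawn splits of the libraries was 560. Of 100 splits, with the real grouping among them, 24 gave 811 genes or more. The range of p from 0.05 to 0.10 held more genes, 911. limma-voom, here and below with quality weights for the libraries, called 0 genes and listed 891 at an unadjusted p of 0.05. DESeq2, run with its default settings on the table of 27607 genes, gave an adjusted p for 18374 genes, called 4, 1 higher and 3 lower, and listed 1098 at an unadjusted p of 0.05. On the 14594 genes that edgeR tested, an alternative added after the data were seen, DESeq2 called 5 genes and listed 960. On simulated counts with 200 changed genes per draw, 17.0% of the DESeq2 calls were false, against 4.10% for edgeR. The simulated genes varied independently of each other, and the shares would differ with another number of changed genes. They therefore do not give the share of false calls among the genes called here. The edgeR count rose to 2 genes when non-slick 4 was left out.

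**Figure D1:**
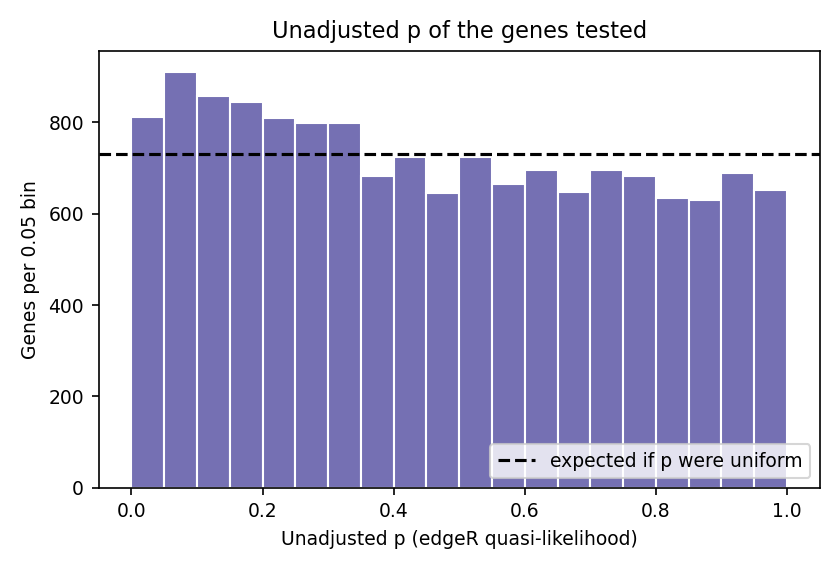
Histogram of the unadjusted p of edgeR's quasi-likelihood test for the 14594 genes tested; each bar is the number of genes in a bin of 0.05, and the dashed line is the number that uniform p-values would give. The first bin held 811 genes, against 729.7 on the dashed line and a median of 560 in other drawn splits of the libraries. The second bin was higher, at 911 genes, so the smallest p-values form no peak.

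The fitted differences were small for most genes. The median absolute log2 fold change was 0.14, and the median standard error was 0.18. The 95% confidence interval of 11475 genes (78.6%) lay inside a 2-fold difference in either direction, and that of 7960 genes (54.5%) lay inside a 1.5-fold difference. Among the 9150 genes with a mean above 10 CPM, 8768 (95.8%) had an interval inside 2-fold, against 2707 (49.7%) of the other 5444. A fitted difference above 2-fold was found for 201 genes, 101 higher and 100 lower in slick explants, none of which passed the adjusted threshold of edgeR.

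The genes with the smallest unadjusted p are given with their values, since none passed the edgeR threshold. Of the first 10, 4 were fitted higher and 6 lower in slick explants, by 1.30-fold to 9.81-fold. The files do not pair their IDs with names. ENSBTAG00000021462 had 106 ± 31.1 CPM in slick and 40.4 ± 16.9 CPM in non-slick explants (SD, n = 6 each). Its log2 fold change was 1.39 (SE 0.25, 95% interval 0.85 to 1.93), and 5 of 6 slick libraries lay above all non-slick libraries. The adjusted p of this gene was 0.650 in edgeR, 0.260 in limma-voom and 8.95e-05 in DESeq2. In edgeR it was 0.0116 without non-slick 4, the library with the highest non-slick value. That value, 72.0 CPM, lay above the lowest slick value, 71.0 CPM. Over 25 alternatives the adjusted p ran from 8.95e-05 to 0.9997. ENSBTAG00000047293 had 15 ± 1.38 CPM in slick and 22.4 ± 1.79 CPM in non-slick explants (SD, n = 6 each), with all 6 slick libraries below all non-slick libraries. The log2 fold change was -0.57 (SE 0.11), with an adjusted p of 0.650 in edgeR and 0.00277 in DESeq2, and of 0.00101 to 0.928 over 25 alternatives.

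ENSBTAG00000054173 was near the limit of detection in slick explants, at 0.496 ± 0.405 CPM, and had 5.00 ± 4.27 CPM in non-slick explants (SD, n = 6 each). Its log2 fold change was -3.29 (SE 0.70), with an adjusted p of 0.839 in edgeR and 3.79e-04 in DESeq2, and of 3.79e-04 to 1.00 over 25 alternatives. In 1 non-slick library, at 13.3 CPM, it lay far above the other 5. ENSBTAG00000008951 had 44.9 ± 14.6 CPM in slick and 24.4 ± 4.50 CPM in non-slick explants (SD, n = 6 each). Its log2 fold change was 0.88 (SE 0.19), with an adjusted p of 0.839 in edgeR and 0.0567 in DESeq2. It was among the 5 genes that DESeq2 called on the genes edgeR tested, an alternative added after the data were seen (adjusted p = 0.0493), and over 25 alternatives its adjusted p ran from 0.0493 to 1.00.

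**Figure D2:**
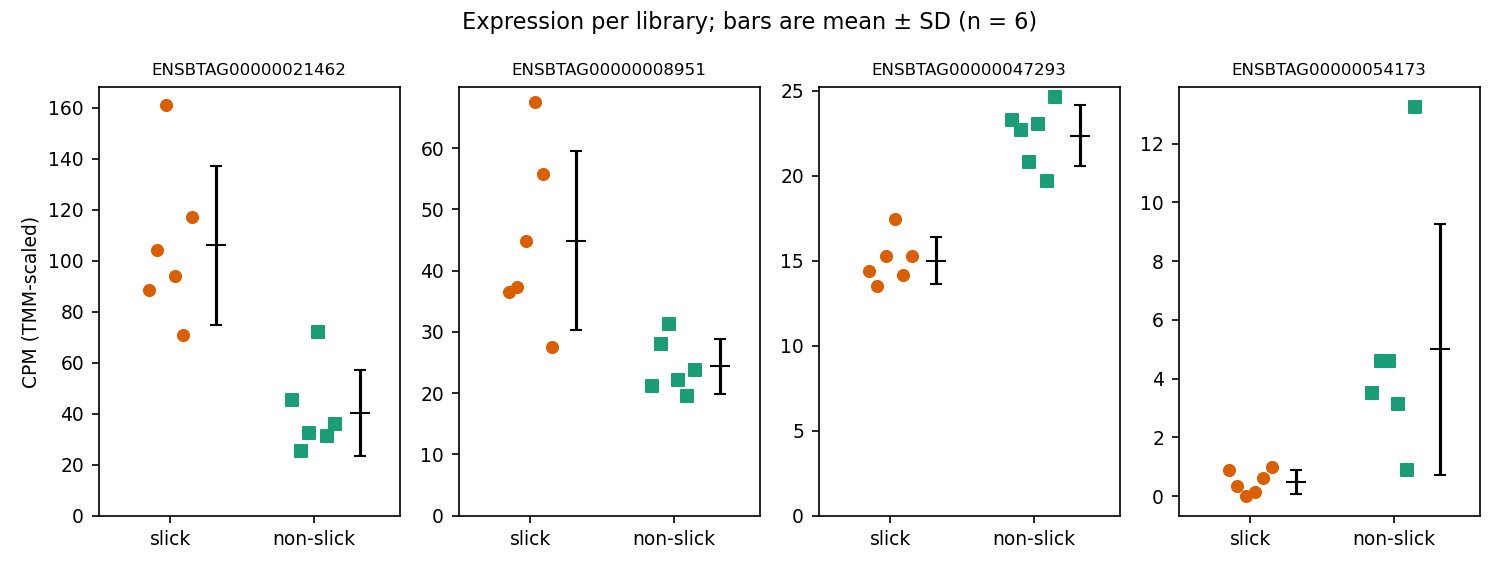
CPM of 4 genes in each library, with slick explants as circles and non-slick explants as squares; bars are the mean ± SD (n = 6). The slick and non-slick values of ENSBTAG00000047293 do not overlap, and 5 of 6 slick values of ENSBTAG00000021462 lie above all non-slick values.

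Slick and non-slick libraries overlapped along the leading axes of variation. The first principal component held 19.9% of the variance and the second 14.2%. Mean scores on the first were 12 ± 31 in slick and -12 ± 20 in non-slick libraries (SD, n = 6 each), a difference within their spread (exact permutation test, two-sided, p = 0.134). On the second they were 9.06 ± 27.8 and -9.06 ± 15.9 (SD, n = 6 each, exact permutation p = 0.199). The slick 4 library lay farthest out on the first component, at 62.96.

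**Figure D3:**
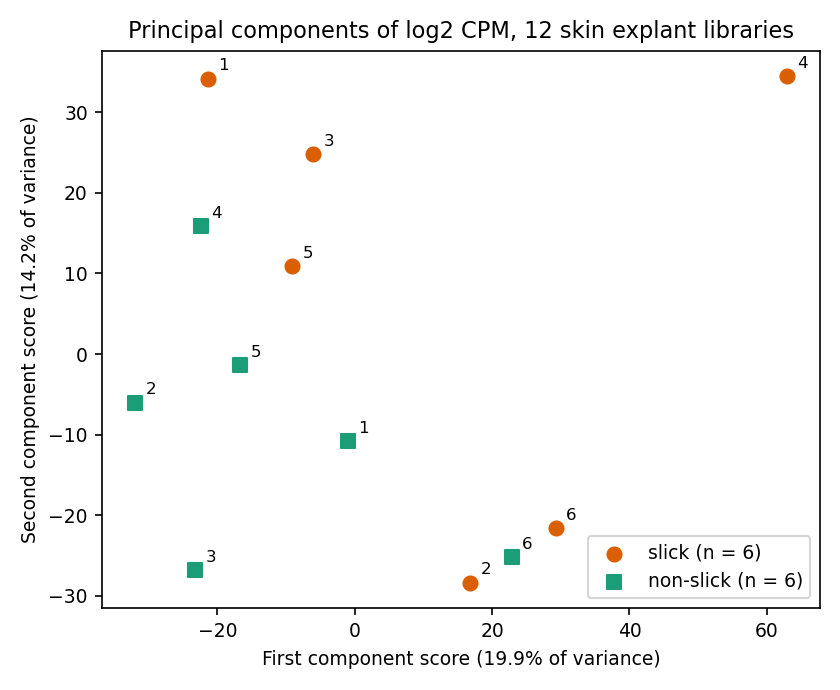
Scores of the 12 libraries on the first and second principal components of log2 CPM, with slick libraries as circles, non-slick libraries as squares and the replicate number beside each point. Libraries of both genotypes overlap, and slick 4 stands apart at 62.96 on the first component.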

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

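The total count of slick 2, 10903164, lay far below the other slick libraries: its gap to the nearest was 0.663 of the range of the group. ENSBTAG00000054173 had 13.3 CPM in 1 non-slick library, with a gap to the nearest of 0.700 of the range. These were 2 of 18 groups of values examined, and chance marks about 1 in 20 groups. Neither was given an explanation.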

How the results depend on the processing

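The edgeR count of 0 genes stayed at 0 at an adjusted p of 0.10, with DESeq2 size factors, upper-quartile factors, no filter, a stricter filter, no robust estimation or 1 surrogate variable, and with limma-voom. Chosen after seeing the data, it also stayed at 0 with the TMM factor as a covariate, with all libraries thinned to the smallest total, and without slick 2 and 4 together. DESeq2 called 4 genes, 1 higher and 3 lower. On the genes edgeR tested, also added after seeing the data, it called 5, 2 higher and 3 lower. The 4 calls are set beside edgeR below. With 1 library left out, edgeR called 0 to 2 genes (0 to 1 higher and 0 to 1 lower); the 2 came without non-slick 4. The number at an unadjusted p of 0.05, 811, a result added after the data were seen, became 1398 with no filter, which tests 20768 genes, and 520 without slick 2 and 4 together. It ran from 551 without slick 4 to 1212 without non-slick 6. Each of the 4 genes given by ID kept its direction in 25 of 25 alternatives. They were picked for a small p in these same libraries, so this is no support for a difference. An adjusted p below 0.05 was reached in 3 of 25 alternatives by ENSBTAG00000021462 and in 2 each by ENSBTAG00000047293 and ENSBTAG00000054173. ENSBTAG00000008951 reached it in 1 of 25. Apart from the edgeR fit of ENSBTAG00000021462 without non-slick 4, all of these were DESeq2 fits. Replicate numbers rise with the number in the library name within each genotype, so a shared replicate number is no sign of a pair. Any other pairing stays open. Same-numbered deviations correlated at -0.09 to 0.26, and 4 of 12 libraries (numbers 5 and 6) matched their own number best. With the replicate block edgeR called 0 genes and listed 858 at an unadjusted p of 0.05. The planned results on the prolactin receptor gene, genes near it, gene lists and mitochondrial counts were not run, since the reference used here held no Ensembl IDs to match. The difference in genes detected, -138.8, became 120.5 at a minimum of 10 counts and 14.1 without slick 2. Thinned to the smallest total, 11330 of 13726 tested genes had an interval inside 2-fold, against 11475 of 14594; depth as a limit was not tested further.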

Other observations

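The test of the edgeR count against other splits, the test of scaling, the fits that set slick 4 beside the other libraries, and the limits behind the gene with absent counts were chosen after the result was seen. The counts at an unadjusted p and without overlap, DESeq2 on the filtered genes, the thinned counts and the test of spread were added after edgeR had called 0 genes, and their comparison with other splits was fixed before those splits were run. The split examined further was picked because it called the most genes.

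A gene had no count in 4 non-slick libraries while all 6 slick libraries expressed it, at 8.59 ± 4.13 CPM (SD, n = 6). The remaining non-slick libraries had 7.96 and 1.35 CPM. It was the 1 gene with at least 3 libraries above 5 CPM and at least 3 below 0.2 CPM. It did not pass the edgeR threshold (adjusted p = 0.839), and its unadjusted edgeR p of 0.0538 was also above 0.05.

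The number of genes at each threshold was set against splits of the 12 libraries into 6 and 6, the real split counted among them. Any split gives at least the edgeR count of 0, so that its 100 of 100 splits decided nothing; the highest other gave 233. Chance was not excluded for the other counts. At an unadjusted p of 0.05, 24 of 100 splits gave 811 genes or more; splits other than the real one had a median of 560, and the highest gave 2984. The genes whose groups did not overlap numbered 41 (0.281% of those tested, where chance gives 0.216%). Of all 462 splits, 88 gave as many; the splits other than the real one had a median of 22, and the highest gave 374. On the filtered genes DESeq2 called 5, 36 of 100 splits gave as many; the splits other than the real one had a median of 3, and the highest gave 1047.

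With its default settings DESeq2 called ENSBTAG00000021462, ENSBTAG00000047293, ENSBTAG00000054173 and ENSBTAG00000004862, and not ENSBTAG00000008951. The log2 fold change of ENSBTAG00000004862 was -2.31 (SE 0.42), with an adjusted p of 3.67e-04 in DESeq2. It ran from 2.15 to 3.86 CPM in slick libraries and from 2.41 to 29.2 CPM in non-slick libraries. In edgeR and DESeq2 the log2 fold changes were -0.574 and -0.576 for ENSBTAG00000047293 and 1.391 and 1.388 for ENSBTAG00000021462. They were -3.29 and -3.32 for ENSBTAG00000054173, and -2.30 and -2.31 for ENSBTAG00000004862. Larger fold changes thus do not explain the DESeq2 calls. For ENSBTAG00000047293 the SE was 0.109 in edgeR and 0.115 in DESeq2, yet unadjusted p was 7.90e-05 and 6.03e-07. The SE of the others was smaller in DESeq2. The step from SE to p was not tested. The 4 genes that DESeq2 called were examined for technical causes. After thinning every library to the smallest total 3 of the 4 stayed called, which argues against unequal sequencing depth as the cause of these 3 calls. The call of ENSBTAG00000047293 ended at an adjusted p of 0.0634, as its log2 fold change went from -0.58 (SE 0.12) to -0.55 (SE 0.13). TMM and upper-quartile factors moved the 4 fold changes by at most 0.0617 SE, too little to test the scaling between libraries, which stays open. In the 12 DESeq2 fits that left out 1 library, ENSBTAG00000021462 and ENSBTAG00000047293 were called each time. ENSBTAG00000054173 was called in 10 of 12 and ENSBTAG00000004862 in 6 of 12, so these 2 calls depend on which library is left out. The DESeq2 total ran from 3 without slick 4 to 17 without non-slick 6, with 13 without slick 5, 10 without non-slick 1, 8 without non-slick 4, and 7 without non-slick 3, slick 1, slick 2 or slick 6. A genotype effect on these genes and chance both stay open.

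The split that called 233 genes placed 3 slick and 3 non-slick libraries on each side, so it does not follow genotype. It was picked as the highest of the drawn splits, so a structure of the samples is possible but was not tested. The split also separates the TMM factors, which follow the make-up of the counts: 1.01 to 1.11 on 1 side and 0.918 to 0.980 on the other. Thinning every library to the smallest total left 301 genes, which argues against unequal sequencing depth as its cause. The 10 most abundant genes held 5.08% to 6.38% of the counts in slick and 5.29% to 6.69% in non-slick libraries, so no few genes took most of the counts. Removing the 19 genes that were among the 10 most abundant of any library left 254 calls. With so small a share of the counts this removal could change little and decides nothing further. The factors stayed apart (1.01 to 1.09 and 0.9275 to 0.9752), so a wider difference in the make-up of the libraries stays open. Without slick 4 the split called 44 genes. Leaving out any other library gave 41 to 1002, the 1002 without non-slick 5, and 2 of them gave no more than 44. The part played by slick 4, which stands apart, therefore stays open. On the first principal component the side with the higher factors held slick 4 (62.96), slick 6 (29.29), non-slick 6 (22.84) and slick 2 (16.76). It also held non-slick 1 (-1.01) and non-slick 5 (-16.69), and the other side ran from -31.99 (non-slick 2) to -6.03 (slick 3). Sire, plate and batch were not given per library and were not tested.

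Whether slick explants vary more than non-slick explants was tested as a hypothesis. The SD of log2 CPM was larger in slick explants for 53.1% of 14594 genes, and without slick 4 for 48.3%. The share was within that of other splits (one-sided exact permutation p = 0.354), so the test gave no sign of a larger spread in slick explants.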
